A study of Neodiprion lecontei and Lasioglossum albipes and Dufourea novaeangliae with 3 samples.

How the data were processed

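DNA methylation was measured by MethylC-seq, in which bisulfite turns unmethylated cytosines into uracil while 5-methylcytosine stays, so that sequencing reads give the methylated share at each cytosine. Per the labels' protocols, genomic DNA was extracted by phenol-chloroform from single whole bodies, pooled by species, converted and sequenced as 1 library per species. The pools held 30 adult females of the sawfly Neodiprion lecontei with the eggs removed, 6 social adult females of the sweat bee Lasioglossum albipes and 4 adult females of the bee Dufourea novaeangliae. The aligner, the genome builds, the conversion rate and any read filter are not given in the sources used here.

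The authors deposited 1 table per library with 1 entry per CpG dinucleotide and no header. Neighbouring positions are never adjacent bases, so both strands of a CpG were taken as merged. The count columns deposited by the authors hold the reads called methylated and unmethylated at each CpG. The fraction that the authors deposited beside them equals the methylated reads divided by both counts, within 0.0001 at every covered CpG. CpGs without a read are listed with a level of 0 and were left out. The last column deposited by the authors is a call of 0 or 1, and the unit of that column is neither a count nor a score. No CpG lies at position 0 and 189, 629 and 133 scaffolds of N. lecontei, L. albipes and D. novaeangliae have one at position 1, so positions were read as counted from 1. Scaffold names are those of the files.

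How the deposited call was made is not stated, so it was tested on the counts. A binomial test that uses the probability of exactly the observed methylated read count, an error rate of 2.2% and Benjamini-Hochberg adjustment at 0.05 over covered CpGs gave the deposited value at 99.99% of CpGs in N. lecontei, 99.998% in L. albipes and 99.9999% in D. novaeangliae. The best rate was 2.2% in each library on a grid of rates. The best one-sided test differed at 55389, 21992 and 4619 CpGs, against 1170, 351 and 10 for the exact-count probability. This form also calls CpGs with fewer methylated reads than the rate would give. Every CpG with 0 methylated reads and at least 265 reads in N. lecontei, 335 in L. albipes or 347 in D. novaeangliae was therefore called, 17141, 5671 and 802 CpGs in that order. Calls with more methylated reads than 2.2% are named calls above the rate below. Their use, alone or with a coverage minimum of 10 or 20 reads, was chosen after the data were seen, and the deposited calls stayed the main result.

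From the counts, weighted levels (methylated reads over all reads), mean per-site levels and shares of called CpGs were computed over CpGs with at least 5 reads. Wilson 95% intervals cover counting error only, since reads without molecular identifiers are not independent molecules. A delete-one jackknife over 100 stretches of equal numbers of CpGs gave a standard error (SE) that describes unevenness along the genome, not differences between animals. Clustering was measured as the share of next covered CpGs within 200 bp that were called, and as Pearson's r of levels between CpGs at set distances. The broad distance classes up to 20000 bp took every 10th CpG as the first of a pair. The bins of 4 bp and the classes of 20 bp took every CpG. Windows of 10 kb needed at least 20 covered CpGs and counted as methylated when at least 10% of these were called. Blocks of methylation, added after the data were seen, joined calls above the rate at most 500 bp apart and needed at least 5 of them. Regions named were the 5 windows of 10 kb per species with the highest weighted level among those with at least 50 covered CpGs, a rule fixed before the data were examined. With 1 library per species there is no replicate error, and no test between species was made.

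Alternatives fixed before the data were examined were coverage minimums of 3, 10 and 20 reads, leaving out CpGs above 3 times the median coverage or scaffolds with fewer than 1000 covered CpGs, own one-sided binomial calls at error rates of 0.005 and 0.01, a fixed level of 20%, thinning every CpG to 5 reads, and other distances, windows and limits. Analyses that need gene positions (genomic features, genes, gene lists, CpG observed/expected and position along genes) were not run, because no annotation of the files' scaffolds was used here. The reference gene table supplied for N. lecontei is of another set of coordinates and was not used. Own calls and the measures were tested on simulated data with the real positions and coverage of 1000000 CpGs per library. The deposited calls were not tested in this way, and CpGs were planted without regard to coverage. Own calls at a rate of 0.005 recovered 99.9% of CpGs planted at a level of 50.0% in N. lecontei, 98.7% in L. albipes and 99.9% in D. novaeangliae. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.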

Results

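Genome-wide CpG methylation was measured in adult females of 3 species of Hymenoptera, the insect order of sawflies, wasps, ants and bees. Neodiprion lecontei is a pine-feeding sawfly from outside the stinging lineages. Lasioglossum albipes is a sweat bee, here from social females, and Dufourea novaeangliae is a solitary bee of the same family. Whether DNA methylation follows sociality across the order cannot be told from these 3 libraries. Each species was represented by 1 library from pooled whole bodies, of 30 sawflies, 6 L. albipes and 4 D. novaeangliae, so values have no replicate error and differences between species were not tested.

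The tables listed 12269553 CpGs in N. lecontei, 17966790 in L. albipes and 14394872 in D. novaeangliae. CpGs were about equally dense along the scaffolds, at 51.2, 53.3 and 51.3 per kb. CpGs with at least 5 reads held 885702514, 438025225 and 575617522 reads, and the median coverage of all CpGs was 61, 18 and 39 reads. At least 5 reads covered 97.0% of CpGs in N. lecontei, 83.5% in L. albipes and 98.7% in D. novaeangliae. At 20 reads L. albipes kept only 46.8% of its CpGs, against 90.3% and 91.8% in the other libraries.

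The sawfly library carried the most CpG methylation and both bee libraries little. The weighted methylation level was 2.78% in N. lecontei (SE along the genome 0.098, Wilson 95% interval 2.778 to 2.780). It was 0.795% in L. albipes (SE 0.026, interval 0.7942 to 0.7958) and 0.752% in D. novaeangliae (SE 0.028, interval 0.7511 to 0.7525). N. lecontei thus stood 3.50 times above L. albipes and 3.70 times above D. novaeangliae, gaps far outside counting error and the SE along the genome. Neither of these errors holds differences between animals or libraries. The levels and their ratios also include any conversion error, which was not measured. CpGs with a deposited call held 88.6% of the methylated reads in N. lecontei, but only 58.3% in L. albipes and 57.4% in D. novaeangliae. Counting every CpG alike gave mean levels of 3.15% (SE 0.107), 1.18% (SE 0.043) and 0.818% (SE 0.031) in the same order. Most CpGs had no methylated read at all, 75.5% in N. lecontei, 90.3% in L. albipes and 87.7% in D. novaeangliae. These shares also depend on coverage, with medians of 61, 18 and 39 reads, so they give no order of the species in methylation.

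The order of the social and the solitary bee was not settled by these libraries. The weighted level of L. albipes was 1.06 times that of D. novaeangliae, a gap of about the size of the SE along the genome. At a coverage minimum of 20 reads it fell to 0.615% in L. albipes against 0.749% in D. novaeangliae, a ratio of 0.822. The mean per-site level likewise went from a ratio of 1.44 to 0.904. The share of deposited calls stood 1.055 times higher in L. albipes at 20 reads, but with only the calls above the 2.2% rate of the deposited test its order turned there too, with 0.721% against 0.897% and a ratio of 0.804. Without a raised coverage minimum L. albipes stayed above D. novaeangliae. The ratio of called shares was 1.65 thinned to 5 reads, 1.37 with own calls at 0.005 and 1.77 at a fixed level of 20%. The minimum of 20 reads kept 46.8% of CpGs in L. albipes but 91.8% in D. novaeangliae, so unlike parts of these genomes were compared there.

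The deposited calls marked 5.77% of covered CpGs as methylated in N. lecontei (687234 of 11906131, SE 0.199). They marked 1.34% in L. albipes (201405 of 15010388, SE 0.064) and 0.917% in D. novaeangliae (130225 of 14202223, SE 0.052). N. lecontei exceeded the bees 4.30 and 6.30 times. In the fitted rule the adjustment within each library left a laxer limit in N. lecontei than in the bees. At a fixed level of 20% in every library the ratios were 3.23 and 5.72. Part of these calls, 8.03%, 10.9% and 3.55%, were at CpGs of high coverage with no more than the 2.2% of methylated reads allowed for error. Without them the called shares were 5.31%, 1.195% and 0.884%. The level at CpGs that were not called was nearly equal in the libraries, 0.356% in N. lecontei, 0.364% in L. albipes and 0.327% in D. novaeangliae. Covered CpGs that were not called despite a level above 20% numbered 1033, 25357 and 783 in that order.

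Methylated CpGs were mostly methylated in part of the reads. Among deposited calls, 65.4% in N. lecontei, 61.4% in L. albipes and 68.3% in D. novaeangliae had a level from 20% to under 80%. Levels of 80% or above made up 15.9%, 25.7% and 20.3% of calls. At a coverage minimum of 20 reads these shares were 15.9%, 17.5% and 20.1%, so the order of the bees turned. With calls above the rate at 20 reads they were 17.4%, 23.9% and 20.9%, and the order of the bees did not turn. The share in L. albipes thus depended on coverage and on the call. The median level at called CpGs was 49.3%, 58.6% and 53.1%, and 52.9%, 62.5% and 54.8% at calls above the rate. In L. albipes the median was 40% among deposited calls with at least 20 reads but 57.1% when only those above the rate were counted. Each library is a pool of animals and of whole-body tissues, and the reads do not separate these.

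**Figure D1:**
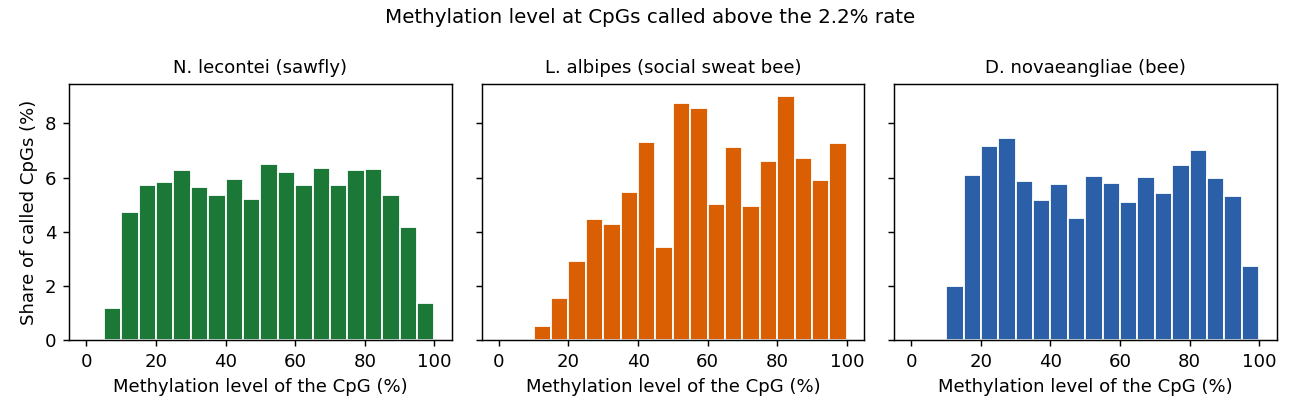
Distribution of CpGs called above the 2.2% rate (y axis, percent of these CpGs) over methylation level (x axis, percent, in bars of 5 points), 1 panel per library. The rightmost bar, for levels from 95% to 100%, holds 1.39% of these CpGs in N. lecontei, 7.27% in L. albipes and 2.75% in D. novaeangliae. The bars under 10% are almost empty in both bees, but this depends on the call. From 5% to under 10% lie 1.18%, 0.050% and 0.017% of these CpGs in the same order. Of own calls at the lower error rate, 5.61%, 1.215% and 3.53% lie there.

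Methylation was strongly clustered in each species. The next covered CpG within 200 bp of a called CpG was itself called in 80.1% of cases in N. lecontei (SE 0.18), 74.7% in L. albipes (SE 0.27) and 72.4% in D. novaeangliae (SE 0.24). After a CpG that was not called these shares were 1.21%, 0.341% and 0.240%. By the deposited calls, windows of 10 kb with at least 10% of CpGs called made up 20.5% of windows in N. lecontei (SE 0.57). They made up 7.42% in L. albipes (SE 0.31) and 5.98% in D. novaeangliae (SE 0.34). With only calls above the rate the shares in N. lecontei and L. albipes were 17.7% and 6.18%. Windows without a single call above the rate made up 76.4%, 88.3% and 84.5%. The tenth of windows with the most calls above the rate held 72.1% of them in N. lecontei, 98.8% in L. albipes and 89.8% in D. novaeangliae.

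The sawfly had longer stretches of methylation than the bees. Calls above the rate formed 6364 blocks in N. lecontei, 6928 in L. albipes and 6678 in D. novaeangliae, numbers that were similar at this joining distance. Their median length was 3240 bp in N. lecontei (quartiles 1690 and 5841), 1067 bp in L. albipes (659 and 1583) and 1267 bp in D. novaeangliae (800.0 and 1965). Blocks held 99.5%, 95.9% and 94.6% of the calls above the rate on 11.7%, 2.50% and 3.57% of the scaffold length, and with joining only within 200 bp these lengths were 9.07%, 1.62% and 1.86%. Within blocks 72.6%, 60.7% and 60.5% of covered CpGs were called. Joining CpGs only within 200 bp cut the sawfly blocks to a median of 776 bp and raised their number to 19091, against 508 bp and 8956 blocks in L. albipes and 501 bp and 8690 blocks in D. novaeangliae. The longest blocks, looked up after the data were seen, were the following. That of N. lecontei spanned positions 18065 to 91655 of scaffold_419 in N. lecontei, with 1762 of 2369 covered CpGs called. Those of the bees were at 4972 to 16228 of scaffold1431 in L. albipes and at 181869 to 190198 of scaffold142 in D. novaeangliae.

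Levels also stayed correlated over longer distances in the sawfly. Pearson's r of levels across pairs of CpGs 2 to 50 bp apart was 0.79 in N. lecontei (SE 0.0016), 0.77 in L. albipes (SE 0.0033) and 0.71 in D. novaeangliae (SE 0.0074). Beyond 200 and up to 1000 bp it was 0.56, 0.35 and 0.27. Beyond 1000 and up to 5000 bp it was 0.34 (SE 0.0037), 0.14 (SE 0.0030) and 0.092 (SE 0.0029), and beyond that up to 20000 bp 0.17, 0.075 and 0.048. These correlations are across sites of 1 library each, which are not independent replicates.

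**Figure D2:**
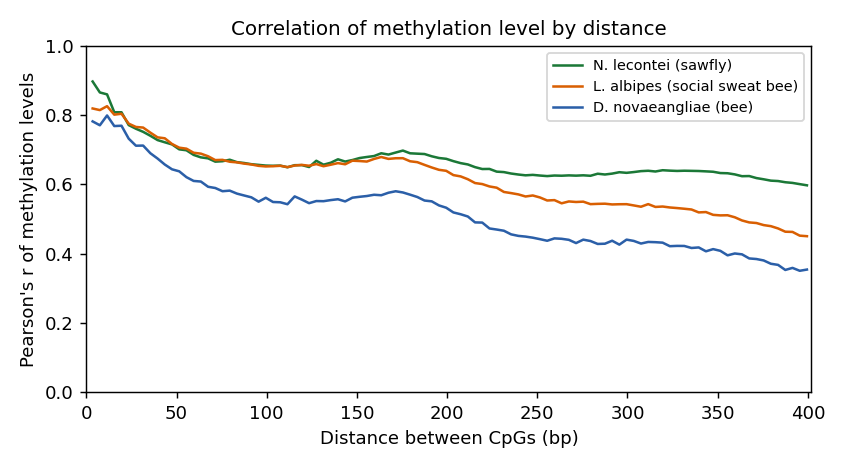
Pearson's r of methylation levels (y axis) between CpGs of 1 library at distances of 2 to 401 bp (x axis, bp, in bins of 4 bp), 1 line per library. The lines start at 0.90, 0.82 and 0.78 in the first bin, and those of L. albipes and D. novaeangliae are highest at 10 to 13 bp, at 0.826 and 0.799. All lines then fall and rise again beyond 120 bp, with r at 0.69, 0.67 and 0.57 over the 20 bp that start at 160 bp.

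The most methylated windows differed between species. In N. lecontei the 5 highest windows of 10 kb lay on 5 scaffolds and had weighted levels from 56.9% to 59.4%. The first was at 250001 to 260000 of scaffold_230, with 279 of 334 covered CpGs called and 67.4 reads per CpG (level 59.4%, Wilson 95% interval 58.75 to 60.03). It was followed by 160001 to 170000 of scaffold_178 at 58.9% and 120001 to 130000 of scaffold_284 at 58.4%, then by 20001 to 30000 of scaffold_634 at 58.1% and 120001 to 130000 of scaffold_413 at 56.9%. In L. albipes the range was 53.9% to 64.8%, led by scaffold2180, whose last CpG lies at position 2350, with 31 of 51 CpGs called. The window at 400001 to 410000 of scaffold108 had the most CpGs of these, with 180 of 384 called and a level of 53.9%. These levels moved with coverage, and over CpGs with at least 20 reads, 11 to 148 per window, the same 5 windows ranged from 60.99% to 79.9%, with scaffold108 next to scaffold2180 at 67.7%. In D. novaeangliae the first 3 were short scaffolds, scaffold1086 at 94.6%, scaffold1137 at 94.6% and scaffold1096 at 54.8%, with 84.3, 232 and 347 reads per CpG against a median of 39 in the library. The next windows, at 70001 to 80000 of scaffold322 and 1110001 to 1120000 of scaffold24, had levels of 33.6% and 33.2%. Genes in these windows were not analysed here.

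In each species methylation lay where CpGs were sparse. CpGs called above the rate had on average 34.2 other CpGs within 500 bp in N. lecontei, 36.5 in L. albipes and 21.2 in D. novaeangliae, against 58.5, 67.3 and 60.997 around the remaining covered CpGs. Among CpGs with at most 20 others within 500 bp, 44.4% were called above the rate in N. lecontei, 16.4% in L. albipes and 24.8% in D. novaeangliae. Among those with more than 80 these shares were 0.182%, 0.0096% and 0.00069%. The decline was steepest in D. novaeangliae, where CpGs with at most 20 others were 1.90% of covered CpGs and held 53.3% of the calls. At 41 to 60 others the called shares were 2.83%, 1.29% and 0.132%. Coverage went with density, from a median of 32 to 103 reads in N. lecontei, 8 to 33 in L. albipes and 30 to 41 in D. novaeangliae between the sparsest and the densest class.

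**Figure D3:**
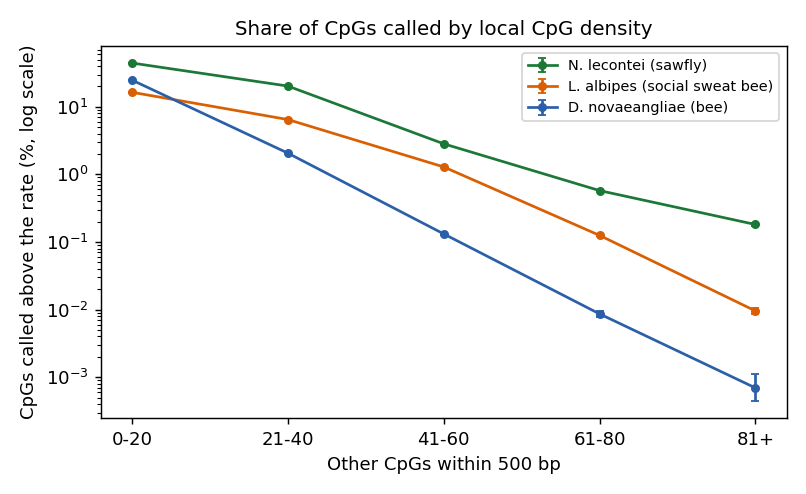
Share of covered CpGs called above the 2.2% rate (y axis, percent, log scale) by the number of other CpGs within 500 bp (x axis, 5 classes), 1 line per library, with Wilson 95% intervals. The share falls from 44.4%, 16.4% and 24.8% in the sparsest class to 0.182%, 0.0096% and 0.00069% in the densest.

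Because the libraries differed in depth, shares were also compared at like coverage. Among CpGs with 20 to 39 reads, 6.10% were called in N. lecontei, 0.926% in L. albipes and 1.28% in D. novaeangliae. At 10 to 19 reads the shares were 3.22%, 1.80% and 0.821%, so the bees changed order between these classes while the sawfly stayed above both. At 5 to 9 reads L. albipes, at 1.80%, lay above N. lecontei, at 0.985%. With every covered CpG thinned to 5 reads and own calls, the shares were 3.91%, 1.15% and 0.697%.

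**Figure D4:**
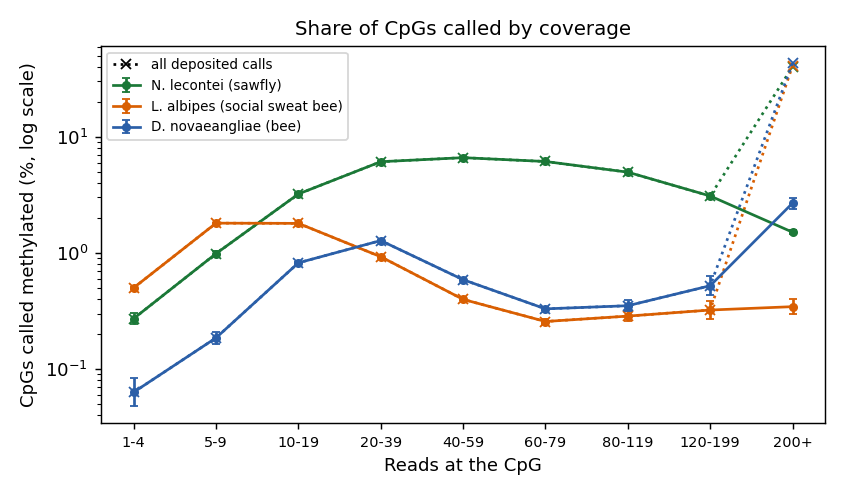
Share of CpGs called methylated (y axis, percent, log scale) by reads at the CpG (x axis, 9 classes), 1 colour per library; solid lines with Wilson 95% intervals are calls above the 2.2% rate and dotted lines all deposited calls. Both coincide below 200 reads, and at 200 or more the deposited calls reach 40.2%, 41.01% and 43.2% while those above the rate are at 1.51%, 0.344% and 2.68%.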

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

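The tests within CpG density, with their use of calls above the rate, were chosen after the result was seen, and the other tests of this part before theirs.

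CpGs with only 1 to 4 reads entered the fit of the call rule and the plot of called shares by reads but no other comparison above. Of their levels, only those at 3 or 4 reads were used, with the coverage minimum of 3 reads. The CpGs with 1 to 4 reads held far more methylated reads than the 3 that a count of 0 allows. Conversion error alone could pass that limit, so it decides nothing about methylation there. Their weighted level was 0.7995% in N. lecontei (2050 of 256405 reads), 1.54% in L. albipes (64178 of 4155074 reads) and 0.555% in D. novaeangliae (1123 of 202477 reads). In L. albipes these CpGs were 1560464 of 17966790, and their level was above the 0.795% of the covered CpGs, while in the other libraries it was below. No unmethylated control was analysed here, so conversion error is part of these levels.

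In the bee libraries the share of called CpGs was higher in the third of CpGs with the lowest coverage than in the third with the highest, by 1.99 times in L. albipes and 2.36 times in D. novaeangliae, and by 3.94 and 2.88 times for calls above the rate. Leaving out CpGs above 3 times the median coverage left a ratio of at least 2.92, which argues against repeats of very high coverage. Within quintiles of local CpG density the ratio of calls above the rate had a median of at most 0.466, but in the sparsest quintile, with 84.2% of these calls in L. albipes and 95.7% in D. novaeangliae, it was 0.609 and 1.003. The common ratio over quintiles (Mantel-Haenszel, coverage limits of the whole library) was 0.793 and 1.04, so the fall with coverage is consistent with methylated CpGs lying in CpG-poor sequence that was covered less. A loss of methylated reads at a locus stays open, with rho between relative level and relative coverage within blocks at -0.16 in L. albipes and -0.087 in D. novaeangliae, and base composition was not tested.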

How the results depend on the processing

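The restriction to calls above the 2.2% rate, alone or with a coverage minimum, and the joining distances of blocks were chosen after the data were seen; the other settings were fixed before. N. lecontei stayed above both bees in weighted level, mean level and called share under every setting run. Among CpGs with 5 to 9 reads alone, however, L. albipes lay above N. lecontei, with called shares of 1.80% against 0.985%. The weighted levels of that class were 1.95% and 1.15%, and L. albipes also lay above at 1 to 4 reads. Among the alternatives of the main measures, 325 kept their value within the limits set, 76 moved and 4 turned the order of the bees. With a coverage minimum of 10 and of 20 reads the ratio of the weighted level of L. albipes to D. novaeangliae went from 1.06 to 0.992 and 0.822, and with 20 reads the ratio of the mean level to 0.904; the mean level of N. lecontei was then 4.38 times that of L. albipes. Weighted levels left their counting interval under most settings. In N. lecontei they were 2.781% and 2.787% at minimums of 10 and 20 reads, 3.01% without CpGs above 3 times the median coverage and 2.97% on scaffolds with at least 1000 covered CpGs. In L. albipes they were 0.801%, 0.746% and 0.615% at 3, 10 and 20 reads, 0.952% without high coverage and 0.845% on large scaffolds. In D. novaeangliae they were 0.7488% at 20 reads, 0.741% without high coverage and 0.733% on large scaffolds. The mean level of L. albipes was 1.02% and 0.739% at 10 and 20 reads. The called share stayed within 1.5 times of its value except in L. albipes with calls above the rate at 20 reads, where it was 0.721%, which is 0.804 times that of D. novaeangliae, while that of N. lecontei was 7.63 times higher.

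The median level at called CpGs moved with the call. In N. lecontei it was 53.0% without high coverage, 50.7% with own calls at a rate of 0.01, 57.7% at a fixed level of 20%, 52.9% above the rate, and 52.94% and 53.01% above the rate at 10 and 20 reads. In L. albipes it was 53.8% and 40% at 10 and 20 reads, 63.2% without high coverage, 55.3% at the fixed level, 55.6% with own calls at 0.005 and 62.5% above the rate, with 57.1% above the rate at 20 reads, so most of the fall to 40% came with the calls of few methylated reads. In D. novaeangliae it was 54.8% without high coverage, 50% and 45.7% with own calls at 0.01 and 0.005, 58.1% at the fixed level, 54.8% above the rate, and 54.84% and 54.5% above the rate at 10 and 20 reads. The share of calls with a level under 20% is 0% at the fixed level by construction. Otherwise it was 11.5% without high coverage and 11.6% above the rate (11.68% and 12.1% at 10 and 20 reads) in N. lecontei, and 22.4% with own calls at 0.005 in D. novaeangliae. In L. albipes it was 31.3% at 20 reads, 1.68% without high coverage, 5.42% and 8.38% with own calls at 0.01 and 0.005, and 2.15% above the rate (2.88% and 6.38% at 10 and 20 reads). The correlations by distance at 20 reads, from the shortest class, were 0.793, 0.684, 0.567 and 0.346 in N. lecontei, 0.803, 0.715, 0.336, 0.0940 and 0.0437 in L. albipes, and 0.734 and 0.581 in D. novaeangliae. At 10 reads they were 0.797, 0.699, 0.361, 0.129 and 0.0647 in L. albipes and 0.730 at the shortest in D. novaeangliae, and at 3 reads 0.761 and 0.644 in L. albipes. After a CpG not called, the called share was 0.181% in L. albipes at 20 reads and 0.145% in D. novaeangliae within 50 bp. Methylated windows were 3.78% in L. albipes and 2.55% in D. novaeangliae at a limit of 20% called, 9.35% in D. novaeangliae at 5%, and 4.86% in L. albipes with 1 kb windows. Except where the construction shows it, the cause was not tested. Depth limits L. albipes most, since only 46.8% of its CpGs had at least 20 reads. The settings listed for analyses by gene or feature were not run, for want of an annotation. Leaving out a replicate was not possible. No paired analysis was possible because each species had 1 library.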

Other observations

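The tests of conversion and of r at 320 bp, the limit of 1.5 times the median coverage, and the use of the thinned reads as a test of read depth were chosen after the result was seen, though the thinning itself was fixed before; the other tests of this part were set before theirs.

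Whole scaffolds differed widely in methylation. Among scaffolds with at least 1000 covered CpGs, 630 of 1547 in N. lecontei, 391 of 931 in L. albipes and 130 of 393 in D. novaeangliae had no CpG called above the rate. The highest shares were 48.1% on scaffold_1467 of N. lecontei, 30.7% on scaffold851 of L. albipes and 10.2% on scaffold712 of D. novaeangliae, against medians over scaffolds of 0.698%, 0.202% and 0.304%.

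In D. novaeangliae 4 of 1106 scaffolds with at least 20 covered CpGs had a level above 80%, and none did in the other libraries. These scaffolds were chosen after their values were seen. They were scaffold1086 (94.6%, last CpG at 587), scaffold1137 (94.6%, last CpG at 1087), C1003162 (93.5%, last CpG at 260) and scaffold1124 (90.6%, last CpG at 1219). Their coverage was 84.3, 232, 25.8 and 385 reads per CpG.

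The share of called CpGs was 4.30 and 6.30 times higher in the sawfly library than in the L. albipes and D. novaeangliae libraries. With every CpG thinned to 5 reads and own calls the smaller ratio was 3.39, which argues against read depth. The level at CpGs not called in N. lecontei minus that in L. albipes was -0.0081 percentage points, which argues against incomplete conversion in the sawfly. Without CpGs above 3 times the median coverage the smaller ratio was 4.23, so repeats of very high coverage do not account for it. The species differed also in pool size, rearing, place of collection and library, and as these coincide with the species in this design, a difference between species may be one of several open explanations.

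The correlation of levels did not fall steadily with distance but rose again near the length of DNA on a nucleosome and its linker. The largest smoothed r beyond 120 bp lay at 176 bp in N. lecontei, 169 bp in L. albipes and 172 bp in D. novaeangliae, and r over 20 bp from 160 bp on exceeded the mean of those from 100 and from 220 bp on by 0.045 (SE 0.0011), 0.056 (SE 0.0015) and 0.065 (SE 0.0029). Without CpGs above 1.5 times the median coverage the smallest rise was 0.052, which argues against collapsed tandem repeats. From 240 over 320 to 400 bp r went from 0.63 over 0.64 to 0.59 in N. lecontei but fell throughout in L. albipes (0.56, 0.53, 0.45) and D. novaeangliae (0.44, 0.42, 0.35), where the excess at 320 bp over the mean of its flanks, at least 0.026 in each library, is a shoulder and not a second rise, so that a regular spacing of nucleosomes may be named only as a hypothesis. Fragments that cover both CpGs stay open, because the rise above the median coverage was 0.58, 0.72 and 0.72 times that at lower coverage.

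The mean number of CpGs around sites called above the rate was 0.59, 0.54 and 0.35 times that around other sites in N. lecontei, L. albipes and D. novaeangliae. Coverage does not account for it, since the ratio was at most 0.637 in every coverage quintile of each library. Loss of methylated cytosines by deamination could leave fewer CpGs, but the ratio of at most 0.586 is the observation itself and no test of that hypothesis, which stays open together with base composition.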
